A study of Mus musculus with 8 samples.

How the data were processed

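Total RNA was extracted from long bones of male Hyp and WT mice aged 12 days, with 2 bone samples of 1 genotype combined per RNA, and labelled with biotin, per the labels. There were 8 arrays, 4 per genotype, and the labels describe the 4 of a genotype as separate samples. They do not say from how many animals each came, so the p-values measure the spread between these RNA samples.

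The deposited table holds 1 value per probe set and array. RMA is named for it per the submitters' processing notes, with no version given in the sources used here, and RMA gives values on the log2 scale. The median of the 8 values of each probe set was 0 within 5e-07, so the deposited log2 values had been centred per probe set, a step that no label records. The log base is not stated. It was taken as 2, since single probe sets spanned up to 8.92 units over the arrays, more than the 4.8 units that a 16-bit scanner covers on a log10 scale. Differences between arrays are kept by the centring, but levels, signal over background and detection cannot be read. Array medians lay between -0.0082 and 0.0082, and no 2 arrays held the same values (SD of the difference between 2 arrays from 0.168 to 0.311). For arrays, their number limits the precision, and the median SE of a difference was 0.081.

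Of 45101 probe sets 64 controls were left out and 45037 tested. The platform annotation gave 1 gene symbol for 34945, several for 932 and no symbol here for 9160. Symbols were updated through gene identifiers in a RefSeq table of the assembly GRCm38.p6, which held 34741 of the probe sets with 1 symbol. That table was used only for names and for the order of genes on a chromosome. Probe sets with several genes or none were tested but not named.

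Hyp was compared with WT in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, 1 fit for all probe sets, no covariate, two-sided, with Benjamini-Hochberg adjustment over the probe sets and a threshold of 0.05. Positive differences are higher in Hyp. Errors marked SE come from this fit, and those marked SD are between the 4 arrays of a group. For genes, the values of all probe sets with that 1 symbol were averaged per array, and 18193 genes were fitted and adjusted in the same way. Of these genes 9010 had more than 1 probe set, and the report says for which named genes the probe sets did not all pass.

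Before the data were examined, 46 lists of genes were fixed for bone cells, matrix, signalling pathways, other cell types that long bones hold, and stress and metabolism. Each was tested with camera in limma on genes measured (at least 5 per list), adjusted over the 46 lists. Camera sets the genes of a list against all other genes, and its preset correlation of 0.01 between genes was used. The test was repeated with a correlation estimated for each list, which gave no list past the threshold, and with fry. Counts per list are given adjusted over all genes and adjusted over the list alone. The genes named were set by a rule fixed at the same time: Phex and Fgf23 with all probe sets; the 10 largest increases and 10 largest decreases among probe sets past the threshold with 1 symbol and no overlap between groups, 1 probe set per gene; and, from each list that passed or held at least 2 changed genes, up to 4 genes with the smallest p. Any other gene is said to be named after its values were seen. Some genes stand in more than 1 list.

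The plan had taken the probe set with the highest mean level for each gene. Centring leaves no such level, so the mean over a gene's probe sets is the value given. Other alternatives were the replicate number as a block, further normalization, array weights, other thresholds, probe sets without a shared-probe suffix, and leaving out each array. A filter on level and a trend in the prior variance need levels and were not run. Added after the data were seen were a robust prior, a filter on the SD over the arrays, the probe set with the largest SD per gene, leaving out both WT replicate 3 and Hyp replicate 2, and the muscle list mean as a covariate. Differences of list means between 4 and 4 arrays were tested with a two-sided exact permutation test, whose smallest p is 0.029.

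The procedure was tested on simulated data with the spread of the 45037 probe sets in this comparison. It recovered 48 of 67 probe sets changed by 0.5 on the log2 scale, all 67 changed by 1 and all 66 changed by 2, with 6 false calls. The simulated probe sets were drawn independently of each other and few were changed, so these rates need not hold in the data. In a simulation over 18193 genes, 1 list shifted by 0.3 was found and none of the other lists was called by camera. Its genes were drawn independently of each other, so it could not show false calls of lists whose genes vary together. In the data, the correlations estimated for the lists that passed ranged from 0.034 (BMP and TGF-beta signalling) to 0.83 (skeletal muscle markers), against the preset 0.01.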

Results

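RNA from the long bones (tibia and femur) of male mice aged 12 days was hybridised to 8 microarrays, 4 of Hyp mice and 4 of wild-type (WT) mice. Hyp mice carry a deletion at the 3′ end of Phex on the C57BL/6 background and serve as a model of X-linked hypophosphatemia, a disorder of renal phosphate loss and poor bone mineralization. Each RNA came from 2 bone samples of 1 genotype. The values of each probe set were centred on a median of 0 over the 8 arrays, so they show differences between arrays and no level of expression. The first principal component held 39.2% of the variance and separated the genotypes, with the Hyp arrays between -26.7 and -17.7 and the WT arrays between 17.9 and 26.1. The next component (22.6%) placed WT replicate 3 at -38.4 and the other arrays between -10.3 and 17.5.

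The comparison of Hyp with WT bone addresses which genes differ where Phex is deleted, in a series whose title concerns Fgf23 expression and mineralization. Phex, which encodes a membrane endopeptidase of osteoblasts and osteocytes, fell in Hyp bone at both of its probe sets. It fell by 8.31 ± 0.21 (SE, n = 4 per group; limma adjusted p = 5.22e-08) on the log2 scale at 1 of them. At the other it fell by 5.03 ± 0.20 (limma adjusted p = 2.15e-06). The values at the first of these were -4.47 ± 0.52 (SD, n = 4) in Hyp and 3.84 ± 0.12 in WT. Fgf23, the bone-derived hormone that lowers renal phosphate reabsorption, rose by 5.61 ± 0.19 (SE; limma adjusted p = 4.1e-07). Its values were 2.78 ± 0.35 (SD, n = 4) in Hyp and -2.83 ± 0.32 in WT. Every Hyp array lay apart from every WT array for these 3 probe sets. Where the Phex probe sets lie relative to the deletion was not examined here, and a probe set outside it would not check the genotype directly.

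**Figure D1:**
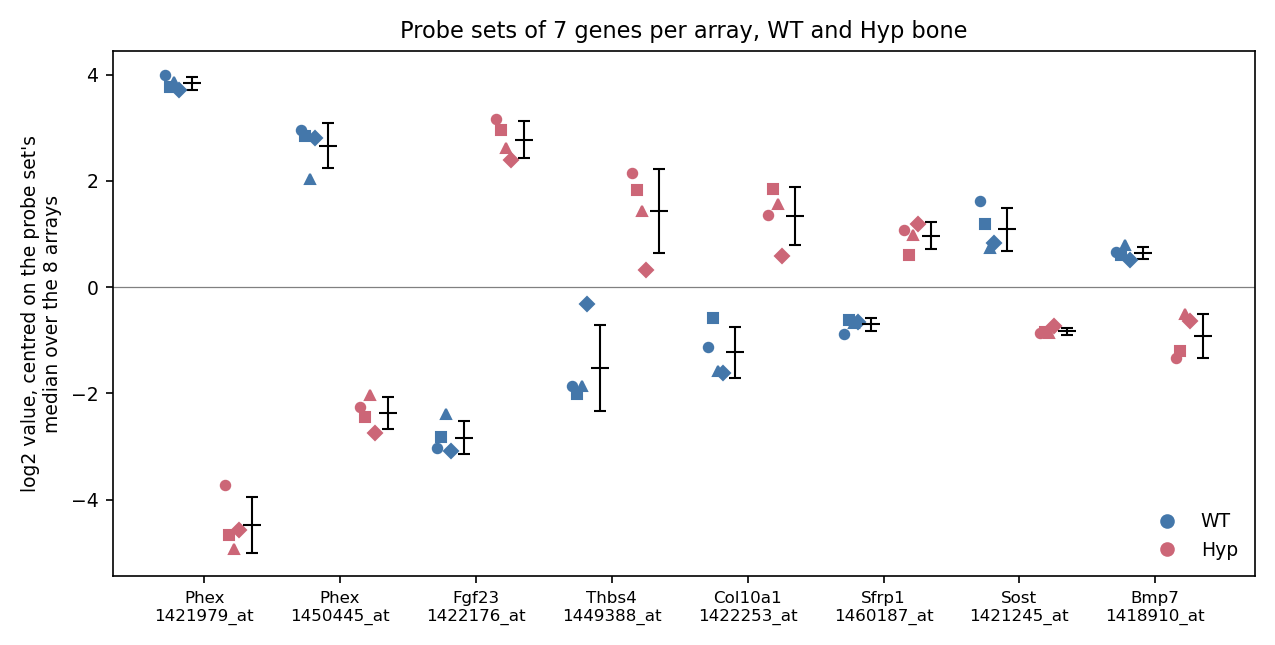
Centred log2 values (y axis) of 8 probe sets of 7 genes (x axis) in the 4 WT and 4 Hyp arrays; symbol shapes mark the replicate numbers (circle 1, square 2, triangle 3, diamond 4), and the black bars give the mean and SD. Phex lies at -4.47 in Hyp and 3.84 in WT at its first probe set, Fgf23 at 2.78 and -2.83, and no Hyp array overlaps the WT arrays in any of the 8 probe sets.

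Among 45037 probe sets, 1452 were higher and 1760 lower in Hyp bone (limma, adjusted p under 0.05), or 7.13% of those tested. The differences were mostly small, with a median size of 0.40 on the log2 scale, and 53 higher and 106 lower probe sets exceeded 2-fold. On gene means, 1190 of 18193 genes were higher and 1150 lower. The groups did not overlap in 6962 probe sets (15.5%), where chance gives 2.86%. After Fgf23, the largest increases were in Thbs4 (thrombospondin 4, a matrix glycoprotein) at 2.95 ± 0.43 (SE) and Col10a1, the collagen of hypertrophic cartilage, at 2.57 ± 0.28. Epcam, an epithelial adhesion molecule, rose by 2.03 ± 0.21 and Cbr2, a carbonyl reductase, by 2.02 ± 0.18. Eln (elastin) rose by 1.87 ± 0.17 and Sostdc1, a secreted antagonist of BMP and Wnt signalling, by 1.71 ± 0.13. Ctsw (cathepsin W), Sfrp1, a secreted Wnt antagonist, and Cyp11a1, the enzyme that starts steroid hormone synthesis, rose by 1.68 ± 0.17, 1.67 ± 0.12 and 1.65 ± 0.17. Adjusted p for these 9 increases ranged from 8.04e-05 to 0.00246.

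After Phex, the largest decrease was in Sost, which encodes sclerostin, the Wnt antagonist of osteocytes, and which fell by 1.92 ± 0.16 (SE). Car12 (carbonic anhydrase 12) fell by 1.92 ± 0.27 and Ptgs2, the inducible cyclooxygenase, fell by 1.73 ± 0.14. Rhpn2 (rhophilin 2) fell by 1.68 ± 0.16, Bmp7 by 1.56 ± 0.17 and Rerg, a small GTPase, by 1.52 ± 0.13. Smoc2, a matricellular protein, Lpar3, a receptor for lysophosphatidic acid, and Sema3d, a semaphorin, fell by 1.5 ± 0.14, 1.5 ± 0.10 and 1.5 ± 0.18. Adjusted p for these 9 decreases ranged from 7.54e-05 to 0.0021. Other probe sets of the same gene passed too for Eln, Sostdc1, Sfrp1, Sost, Ptgs2, Rhpn2, Bmp7, Smoc2 and Sema3d, while 1 of 3 did not for Cyp11a1 and for Car12, and the other probe set of Epcam lay at 0.18 ± 0.09 (adjusted p = 0.261). In 1 group each, a single array lay apart from the other 3 for Thbs4, Sostdc1, Sost, Ank, Ccne1, Cd34, Cd36, Cdo1, Fzd4, Igfbp7, Insig1, Klf4, Mki67, Pcsk5, Plvap and Smpd3. The counts depend on the number of arrays: with 1 array fewer, the higher probe sets numbered 625 without WT replicate 1, between 791 and 958 without any of the other arrays except WT replicate 3, and 2125 without WT replicate 3, and the lower ones 1055 without WT replicate 1 and between 1204 and 1975 otherwise.

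Genes of the osteoblast lineage were mostly lower in Hyp bone. Of 22 measured osteoblast markers, 17 fell and 2 rose, with a list median of -0.498 (camera adjusted p = 1.11e-13; adjusted p = 0.224 with an estimated correlation). Adjusted over the list alone, 18 fell and 2 rose. Cpz, a carboxypeptidase, fell by 1.38 ± 0.11 (SE), Col22a1 by 1.23 ± 0.10, Ifitm5, a membrane protein of mineralizing osteoblasts, by 1.22 ± 0.09 and Tmem119 by 0.75 ± 0.06. The 2 that rose were Mmp13 (collagenase 3) at 0.52 ± 0.06 and, named after its values were seen, Col1a1 at 0.47 ± 0.12 on the gene mean. The probe sets of Col1a1, a chain of the main bone collagen, disagreed: 1 rose by 1.08 ± 0.23 and another lay at -0.14 ± 0.06 (adjusted p = 0.174). Col1a2, another chain of that collagen, is given by probe set only and after its values were seen. Its probe sets lay at -0.24 ± 0.06, -1.06 ± 0.20 and -0.11 ± 0.05 (limma adjusted p = 0.0279, 0.00952 and 0.251), so a rise of this collagen cannot be read from Col1a1.

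Osteocyte markers went both ways, with more lower than higher. Of 26 measured genes 12 fell and 4 rose, with a median of -0.193 (camera adjusted p = 0.000662; adjusted p = 0.402 with an estimated correlation). Adjusted over the list alone, 14 fell and 5 rose. All these values are for the list with Fgf23 and with Phex, the gene deleted in Hyp, in it. Besides Phex, Sost fell by 1.85 ± 0.14 (SE) on the gene mean and Cdo1, which starts cysteine breakdown, by 1.0 ± 0.05. The 4 that rose were Fgf23, Ank, the pyrophosphate transporter, at 0.77 ± 0.10, Tnfrsf11b (osteoprotegerin) at 0.65 ± 0.15 and, named after its values were seen, Mepe at 0.87 ± 0.16. Dmp1, a matrix protein of osteocytes also chosen after its values were seen, lay between 0.07 and 0.23 at its 3 probe sets, with adjusted p from 0.158 to 0.597. Osteoclast markers showed no shift as a list (22 measured, median -0.02, camera adjusted p = 0.641). Car2 and Mmp14 rose by 0.26 ± 0.05 and 0.28 ± 0.06 and Dcstamp, needed for osteoclast fusion, fell by 0.33 ± 0.08. Adjusted over the list alone, 3 rose and 3 fell.

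**Figure D2:**
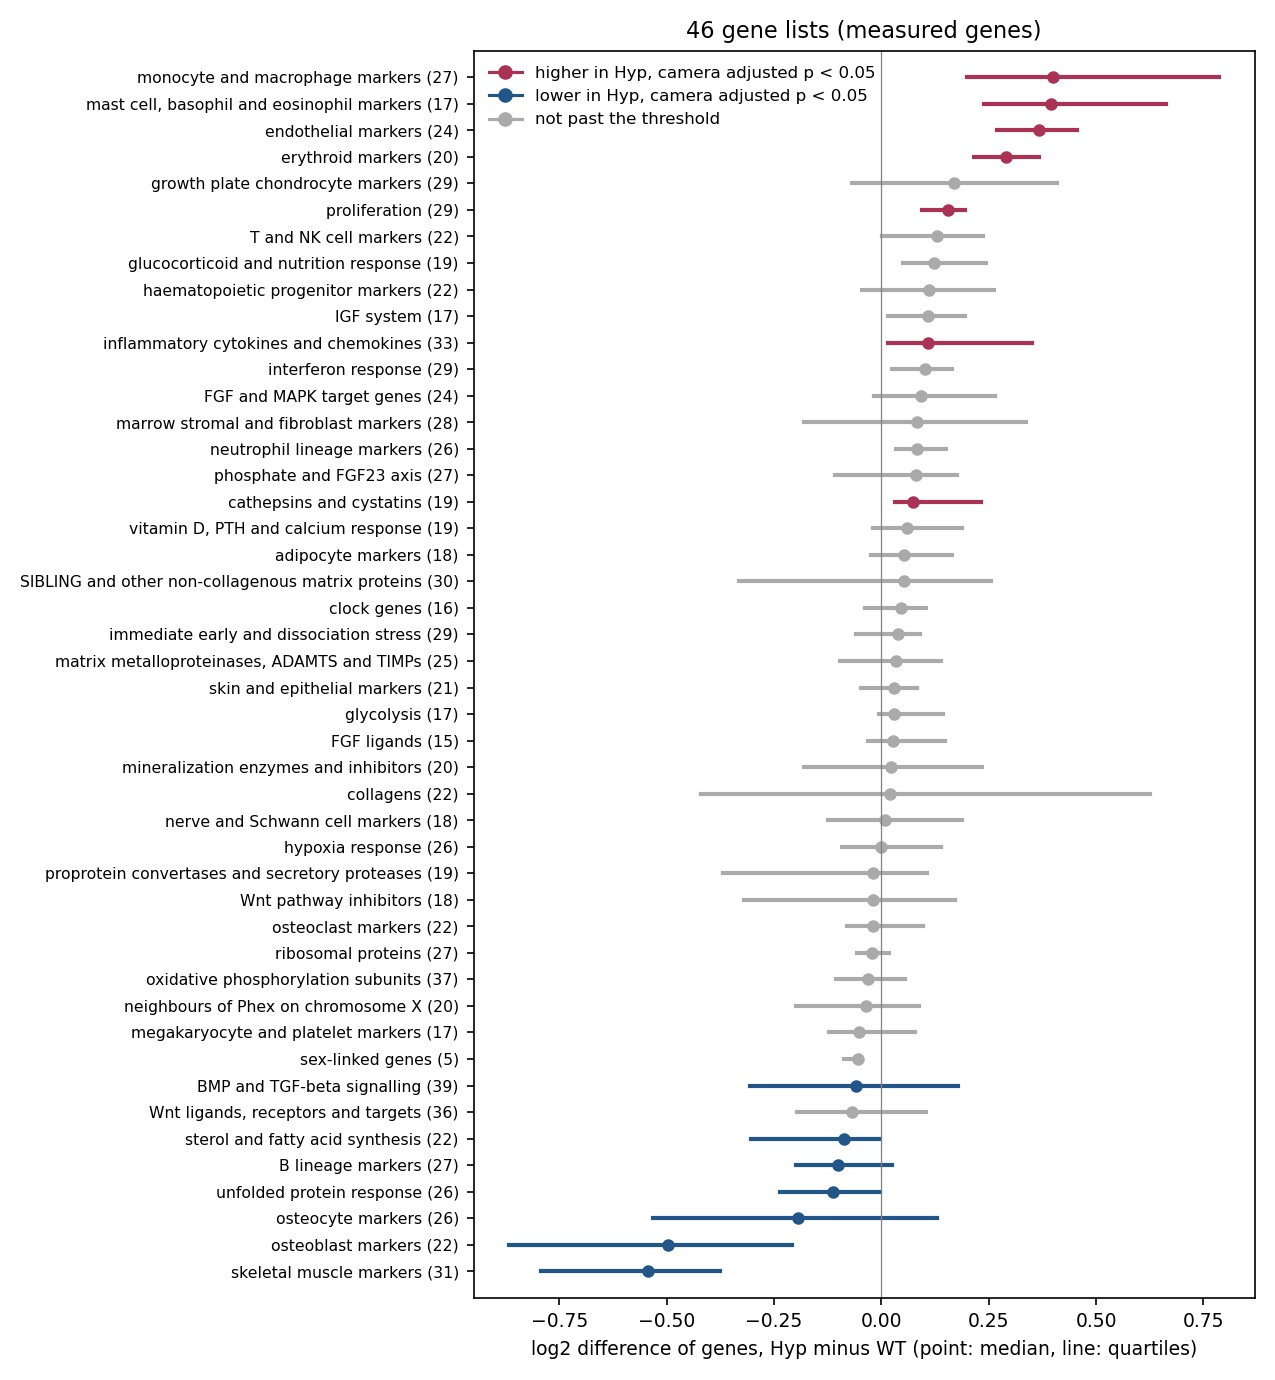
Median (point) and quartiles (line) of the log2 difference Hyp minus WT (x axis) over the measured genes of each of 46 gene lists (y axis, number of genes in brackets); colour marks lists past camera's threshold with its preset correlation. Osteoblast markers have a median of -0.498 and monocyte and macrophage markers one of 0.399, and the low median of skeletal muscle markers rests mostly on WT replicate 3.

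Genes of the phosphate and FGF23 axis changed singly and not as a list: of 27 measured genes 5 rose and 4 fell (camera adjusted p = 0.536), and adjusted over the list alone 7 rose and 4 fell. Sfrp4, a secreted frizzled-related protein with phosphaturic activity, rose by 1.46 ± 0.13 (SE) and Pcsk5, a proprotein convertase, fell by 0.69 ± 0.06. Of 24 measured targets of FGF and MAPK signalling, 4 rose and the rest did not pass (camera adjusted p = 0.0925; adjusted over the list alone, 5 rose and 1 fell). They were Egr2 at 1.19 ± 0.15, Dusp6, a phosphatase of ERK, at 0.77 ± 0.07, Spry1 at 0.56 ± 0.08 and Ier3 at 0.34 ± 0.09. Among 15 other members of the FGF family (the list named FGF ligands, though not all are ligands), Fgf1 rose by 1.13 ± 0.18, Fgf7 by 0.98 ± 0.06, and Fgf13 fell by 0.43 ± 0.05 (camera adjusted p = 0.511 for the list; the same 2 and 1 adjusted over the list alone).

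Wnt pathway inhibitors moved in opposite directions. Of 18 measured, 4 rose and 5 fell (camera adjusted p = 0.47), and adjusted over the list alone 4 rose and 6 fell. Sfrp4, Sostdc1 (gene mean 1.16 ± 0.10, SE) and Sfrp1 (gene mean 1.0 ± 0.07) rose while Sost fell. Named after their values were seen, Sfrp5 rose by 0.21 ± 0.06 and Notum, Wif1, Apcdd1 and Dkk3 fell by 1.24 ± 0.23, 0.95 ± 0.08, 0.49 ± 0.07 and 0.33 ± 0.10. Of 36 measured Wnt ligands, receptors and targets, 2 rose and 5 fell (camera adjusted p = 0.141; adjusted over the list alone, 4 and 10). Ccn5 and Fzd4, a Wnt receptor, rose by 1.33 ± 0.11 and 0.38 ± 0.08, and Ccn4 and Lgr6 fell by 0.71 ± 0.12 and 0.64 ± 0.12. In BMP and TGF-beta signalling, 12 of 39 measured genes fell and 5 rose, with a median of -0.06 (camera adjusted p = 0.0473; adjusted p = 0.351 with an estimated correlation; adjusted over the list alone, 12 fell and 6 rose). Bmp7 fell by 1.19 ± 0.10 and Tgfb2 by 0.41 ± 0.07, while Ltbp2 rose by 0.87 ± 0.12 and Bmp6 by 0.70 ± 0.10. This list missed the threshold without Hyp replicate 2, WT replicate 1 or WT replicate 3 (camera adjusted p = 0.0983, 0.0793 and 0.0553). It also missed it with median centring, quantile and cyclic loess normalization, and under other settings given in the section on processing.

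Enzymes and inhibitors of mineralization included 5 that rose and 5 that fell among 20 measured (camera adjusted p = 0.78; adjusted over the list alone, 6 and 7). Mgp (matrix Gla protein), an inhibitor of calcification, rose by 1.14 ± 0.08 (SE) and Ank by 0.77 ± 0.10, while Car12 fell by 1.08 ± 0.09 on the gene mean and Smpd3, a sphingomyelinase needed for bone mineralization, by 1.04 ± 0.11. Of 19 proprotein convertases and secretory proteases 7 fell and 3 rose (camera adjusted p = 0.0829; the same 7 and 3 adjusted over the list alone). Pcsk6 fell by 1.25 ± 0.11, Pcolce, an enhancer of procollagen processing, by 0.88 ± 0.10 and Galnt3, the glycosyltransferase that protects FGF23 from cleavage, by 0.44 ± 0.06. The 3 that rose, named after their values were seen, were Htra1 at 0.63 ± 0.10, Ece1 at 0.35 ± 0.07 and Ecel1 at 0.26 ± 0.06. Ece1 lay at 0.29 without shared-probe suffix and at 0.2 with its probe set of the largest SD (limma adjusted p = 0.106 and 0.438).

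**Figure D3:**
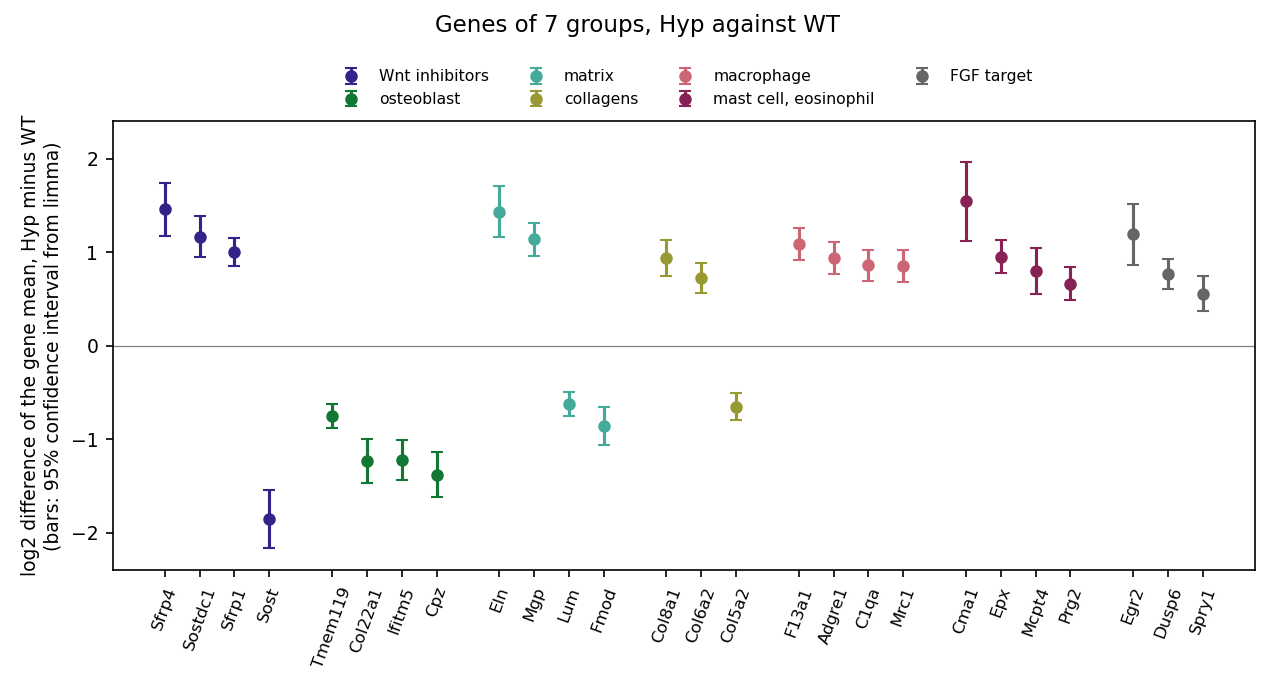
Log2 difference of the gene mean, Hyp minus WT (y axis), with its 95% confidence interval from limma (bars), for genes of 7 groups (colours; x axis). Among the Wnt inhibitors Sfrp4, Sostdc1 and Sfrp1 lie at 1.46, 1.16 and 1.0 and Sost at -1.85, and the macrophage, mast cell and eosinophil genes shown lie between 0.66 and 1.54.

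Collagens split evenly, with 8 of 22 measured genes higher and 8 lower in Hyp bone (camera adjusted p = 0.78; adjusted over the list alone, 9 and 10). Col8a1 rose by 0.94 ± 0.09 (SE) and Col6a2 by 0.72 ± 0.07, while Col22a1 fell by 1.23 ± 0.10 and Col5a2, a fibrillar collagen, by 0.65 ± 0.06. Of 30 non-collagenous matrix proteins (the SIBLING list), 9 rose and 9 fell (camera adjusted p = 0.952; adjusted over the list alone, 10 and 11). Eln (gene mean 1.43 ± 0.12) and Mgp rose, and the small leucine-rich proteoglycans Fmod and Lum fell by 0.86 ± 0.09 and 0.62 ± 0.06. Of 25 matrix metalloproteinases, ADAMTS and TIMPs, 5 rose and 4 fell (camera adjusted p = 0.809; adjusted over the list alone, 5 and 5). Mmp13 rose by 0.52 ± 0.06, and Mmp16, Mmp23 and Adam12 fell by 1.11 ± 0.105, 0.64 ± 0.08 and 0.57 ± 0.07. Of 29 growth plate markers 7 rose and 3 fell, with a median of 0.169 (camera adjusted p = 0.237; adjusted over the list alone, 13 and 4). Col10a1 rose, and Col11a2, Col11a1 and Papss2, which makes the sulfate donor, fell by 1.01 ± 0.10, 0.78 ± 0.06 and 0.41 ± 0.06. Among cathepsins and cystatins 4 of 19 rose and 1 fell (median 0.073, camera adjusted p = 0.0133; adjusted p = 0.362 with an estimated correlation; adjusted over the list alone, 6 and 1). Ctsw, Ctss, Ctsb and Ctsd rose by 1.68 ± 0.17, 0.49 ± 0.06, 0.37 ± 0.05 and 0.30 ± 0.05 and Ctsh, named after its values were seen, fell by 0.30 ± 0.08. Without WT replicate 3 the list's camera adjusted p was 0.0553. Camera compares a list with all other genes and not with 0, and the median difference over all probe sets was 0.022. Its direction was down, with a median and mean above 0, for collagens (0.02 and 0.03), non-collagenous matrix proteins (0.052 and 0.134) and the mineralization list (0.022 and 0.004). For the metalloproteinases the median was 0.035 and the mean -0.03.

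Markers of several marrow and vascular cell types were higher in Hyp bone. Of 27 measured monocyte and macrophage markers 18 rose and the rest did not pass, with a median of 0.399 (camera adjusted p = 1.11e-13; adjusted p = 0.224 with an estimated correlation; 20 rose adjusted over the list alone). F13a1 (coagulation factor XIII A chain) rose by 1.08 ± 0.08 (SE), Adgre1, an adhesion receptor, by 0.94 ± 0.08, C1qa by 0.86 ± 0.07 and Mrc1, the mannose receptor, by 0.85 ± 0.08. Of 17 mast cell, basophil and eosinophil markers 13 rose, with a median of 0.396 (camera adjusted p = 6.36e-10; adjusted p = 0.224 with an estimated correlation; 14 rose adjusted over the list alone). Cma1 (mast cell chymase) rose by 1.54 ± 0.19, Epx (eosinophil peroxidase) by 0.95 ± 0.08, Mcpt4 by 0.80 ± 0.11 and Prg2, the eosinophil major basic protein, by 0.66 ± 0.08. Of 24 endothelial markers 16 rose, with a median of 0.368 (camera adjusted p = 1.85e-10; adjusted p = 0.351 with an estimated correlation; 20 rose adjusted over the list alone). Plvap, Eng (endoglin), Sox17 and Esam rose by 0.59 ± 0.06, 0.51 ± 0.05, 0.49 ± 0.07 and 0.41 ± 0.05. Of 20 erythroid markers 14 rose, with a median of 0.29 (camera adjusted p = 4.1e-08; adjusted p = 0.351 with an estimated correlation; 15 rose adjusted over the list alone). Klf1, the erythroid transcription factor, and Alas2, the first enzyme of haem synthesis in red cells, rose by 0.49 ± 0.07 and 0.48 ± 0.07, and Ermap and Icam4 by 0.44 ± 0.09 and 0.42 ± 0.09.

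Proliferation genes and inflammatory mediators were also higher. Of 29 proliferation genes 11 rose, with a median of 0.155 (camera adjusted p = 3.44e-06; adjusted p = 0.351 with an estimated correlation; 16 rose adjusted over the list alone), among them the cyclins Ccnb2, Ccna2 and Ccne1 at 0.29 ± 0.05 (SE), 0.27 ± 0.05 and 0.27 ± 0.06 and Mki67 at 0.29 ± 0.07. Of 33 inflammatory cytokines and chemokines 10 rose and 1 fell, with a median of 0.108 (camera adjusted p = 0.00604; adjusted p = 0.351 with an estimated correlation; adjusted over the list alone, 14 and 2). The chemokines Ccl3 and Ccl6 rose by 1.16 ± 0.13 and 1.10 ± 0.13 and Il18 by 0.43 ± 0.06, while Ptgs2 fell by 1.13 ± 0.10 on the gene mean. B lineage markers were lower as a list by camera (27 measured, 3 fell and 1 rose, median -0.101, camera adjusted p = 0.0409; adjusted p = 0.666 with an estimated correlation; the same 3 and 1 adjusted over the list alone). Their list mean differed by -0.093 ± 0.093 (SE; exact permutation p = 0.371), and the arrays of the 2 genotypes overlapped. Dntt, Rag1 and Vpreb1, all of early B cells, fell by 0.56 ± 0.09, 0.52 ± 0.12 and 0.41 ± 0.11, and Bank1, of later B cells, rose by 0.34 ± 0.07. This list missed the threshold without Hyp replicate 1, Hyp replicate 3, WT replicate 1 or WT replicate 2 (camera adjusted p = 0.081, 0.188, 0.174 and 0.118). Its median was -0.174 without Hyp replicate 2, -0.036 without Hyp replicate 3 and -0.042 without WT replicate 1.

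Other marrow lists did not pass. Neutrophil lineage markers had a median of 0.084, with 3 of 26 higher (camera adjusted p = 0.0686; 3 adjusted over the list alone): Padi4 at 0.33 ± 0.08 (SE), Il1b at 0.29 ± 0.07 and Csf3r at 0.29 ± 0.06. T and NK cell markers had a median of 0.13, with 4 of 22 higher (camera adjusted p = 0.0698; 7 adjusted over the list alone): Gzmb at 0.32 ± 0.09, Thy1 at 0.26 ± 0.08, Cd4 at 0.26 ± 0.06 and Ccl5 at 0.245 ± 0.07. Progenitor markers had a median of 0.111, with 7 of 22 higher and 1 lower (camera adjusted p = 0.0806; 8 and 1 adjusted over the list alone), among them Cebpa at 0.45 ± 0.08, Tal1 at 0.43 ± 0.07, Lmo2 at 0.33 ± 0.06 and Cd34 at 0.30 ± 0.07. Of 17 megakaryocyte and platelet markers Selp and Nfe2 rose by 0.35 ± 0.08 and 0.33 ± 0.08 (list median -0.052, mean 0.002, camera adjusted p = 0.647; adjusted over the list alone, 3 rose and 1 fell). Of 29 interferon response genes 1, Isg20, named after its values were seen, rose, by 0.46 ± 0.14 (list median 0.102, camera adjusted p = 0.148).

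Skeletal muscle markers had a list median of -0.544 that rested mostly on WT replicate 3, with a smaller part from Hyp replicate 2. Of 31 measured genes only Car3, a carbonic anhydrase of muscle and fat, passed, and it fell by 1.11 ± 0.06 (SE; camera adjusted p = 5.44e-05 for the list; adjusted p = 0.656 with an estimated correlation; 1 fell adjusted over the list alone). The list mean was 1.74 in WT replicate 3 against -0.41 to 0.24 in the other WT arrays, and -0.92 in Hyp replicate 2. Of the 31 genes 25 had their lowest value in Hyp replicate 2. Without WT replicate 3 the median was -0.102 (camera adjusted p = 0.0925), without Hyp replicate 2 it was -0.359 and without WT replicate 1 it was -0.828. With both WT replicate 3 and Hyp replicate 2 left out it turned positive and the list did not pass. Acta1, the main actin of skeletal muscle, named after its values were seen, lay at -1.06 ± 0.77 (adjusted p = 0.465).

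**Figure D4:**
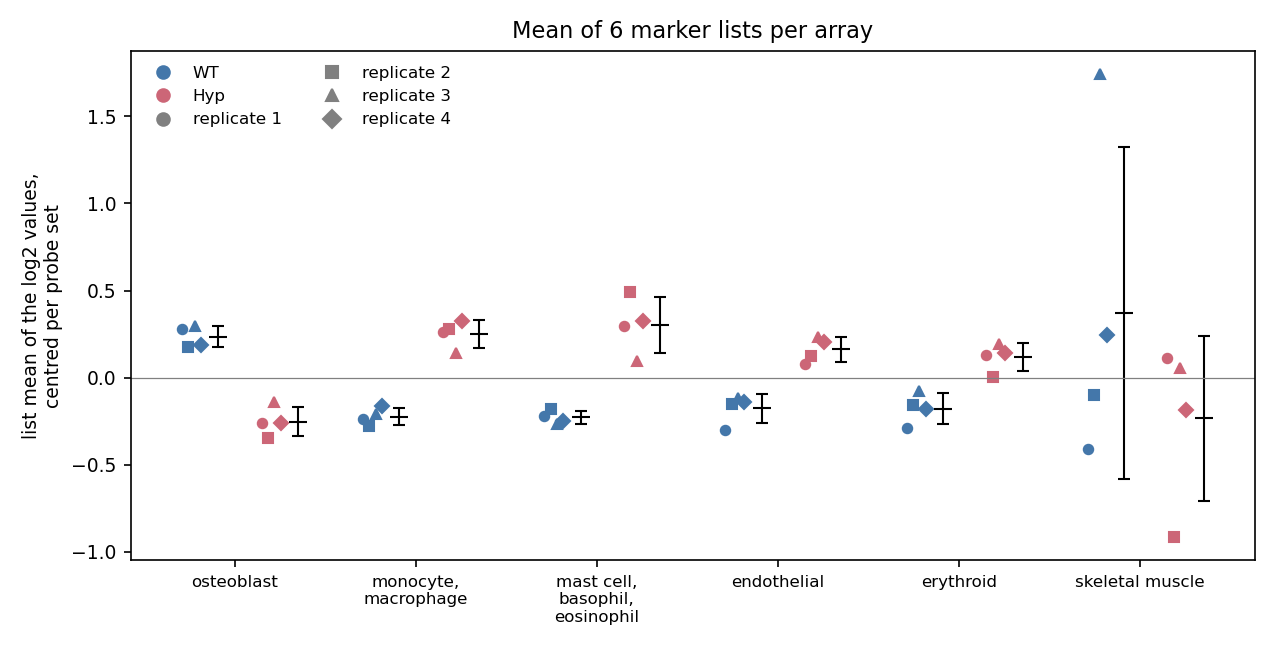
Mean of the centred log2 values (y axis) over 6 marker lists (x axis) in each WT and Hyp array; symbol shapes mark the replicate numbers, and the black bars give the mean and SD of the 4 arrays. The Hyp arrays lie below the WT arrays for osteoblast markers (-0.252 against 0.236) and above them for macrophage, mast cell, endothelial and erythroid markers, and WT replicate 3 stands at 1.74 for skeletal muscle markers.

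Lists of other tissues in or around bone did not pass. Of 28 marrow stromal and fibroblast markers 8 rose and 4 fell (median 0.084, camera adjusted p = 0.345; adjusted over the list alone, 9 and 5). The pericyte genes Pdgfrb and Mcam rose by 0.58 ± 0.05 (SE) and 0.52 ± 0.07, and Gsn (gelsolin) fell by 0.39 ± 0.05. Of 18 adipocyte markers Scd1 and Adipoq (adiponectin) fell by 0.60 ± 0.11 and 0.46 ± 0.13 and Fabp4 rose by 0.55 ± 0.15 (median 0.052, camera adjusted p = 0.641; adjusted over the list alone, 2 and 2). Of 21 skin and epithelial markers Epcam (gene mean 1.11 ± 0.11) and Krt18 (0.70 ± 0.09) rose and Krt10 fell by 0.36 ± 0.08 (median 0.03, camera adjusted p = 0.809; the same 2 and 1 adjusted over the list alone). Of 18 nerve and Schwann cell markers S100b (0.88 ± 0.07) and Egr2 rose, and Fabp7 and Pmp22 fell by 0.56 ± 0.08 and 0.44 ± 0.10 (median 0.009, camera adjusted p = 0.78; adjusted over the list alone, 5 rose and 3 fell).

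Genes of the unfolded protein response, which serve folding and quality control in the endoplasmic reticulum, were lower in Hyp bone. Of 26 measured 10 fell and 1 rose, with a median of -0.112 (camera adjusted p = 0.000195; adjusted p = 0.224 with an estimated correlation; adjusted over the list alone, 13 fell and 2 rose). Chac1 fell by 0.67 ± 0.08 (SE), Manf by 0.35 ± 0.06, the transcription factor Xbp1 by 0.34 ± 0.06 and Edem1 by 0.30 ± 0.05. Ppp1r15a, named after its values were seen, rose by 0.30 ± 0.07. Of 22 genes of sterol and fatty acid synthesis 7 fell and 1 rose, with a median of -0.088 (camera adjusted p = 0.000961; adjusted p = 0.351 with an estimated correlation; adjusted over the list alone, 8 and 1). Insig1, a sterol sensor, fell by 0.54 ± 0.05, Cyp51 by 0.40 ± 0.06 and Scd1 by 0.60 ± 0.11, and the transcription factor Srebf1 rose by 0.30 ± 0.06. The medians of both lists moved widely with the choice of probe sets, as given in the section on processing.

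Among 26 genes of the hypoxia response 3 rose and 4 fell (median 0, mean -0.085, camera adjusted p = 0.345; adjusted over the list alone, 3 and 5). The collagen prolyl hydroxylases P4ha2 and P4ha1 fell by 1.14 ± 0.11 (SE) and 1.11 ± 0.08, and Hmox1 (haem oxygenase) rose by 0.74 ± 0.08. In the IGF system Igf1, Igfbp4 and Igfbp7 rose by 0.48 ± 0.09, 0.47 ± 0.05 and 0.45 ± 0.06 and Irs1 fell by 0.48 ± 0.08 (17 measured, median 0.109, camera adjusted p = 0.0829; the same 3 and 1 adjusted over the list alone). Among 19 genes of the response to vitamin D, PTH and calcium, Mmp13, Tnfrsf11b and Nr4a3 (0.27 ± 0.06) rose and Nr4a2 fell by 0.76 ± 0.07, as did Pth1r, the PTH receptor, named after its values were seen, by 0.24 ± 0.07 (median 0.06, camera adjusted p = 0.47; the same 3 and 2 adjusted over the list alone). Of 29 immediate early and dissociation stress genes Egr2, Ier3 and Gadd45a (0.30 ± 0.07) rose and Klf4 and Gadd45b fell by 0.71 ± 0.07 and 0.26 ± 0.05 (median 0.038, camera adjusted p = 0.809; the same 3 and 2 adjusted over the list alone). Of 19 genes of the glucocorticoid and nutrition response, Per1 and Angptl4 rose by 0.55 ± 0.15 and 0.47 ± 0.09 and Cdkn1a fell by 0.35 ± 0.10 (median 0.122, camera adjusted p = 0.0948; adjusted over the list alone, 3 and 1). Over probe sets without a shared-probe suffix, Angptl4 lay at 0.16 (limma adjusted p = 0.282).

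Of 37 subunits of oxidative phosphorylation Ndufa1, Ndufa5 and Ndufa2 fell by 0.27 ± 0.04 (SE), 0.24 ± 0.05 and 0.23 ± 0.05 (median -0.03, camera adjusted p = 0.0948; 3 fell adjusted over the list alone). Slc16a3, a lactate transporter named after its values were seen, rose by 0.21 ± 0.06 among 17 glycolysis genes (median 0.029, camera adjusted p = 0.233). Per1, named by the rule from the glucocorticoid list, was the 1 changed gene of 16 clock genes (median 0.046, camera adjusted p = 0.809). Slc16a3, Per1 and Isg20 did not pass when adjusted over the glycolysis, clock and interferon lists alone. No ribosomal protein of 27 passed limma's threshold (1 had an unadjusted p under 0.05; median -0.021, camera adjusted p = 0.273), nor any of 5 sex-linked genes (none had an unadjusted p under 0.05; median -0.055, camera adjusted p = 0.315). In the list named neighbours of Phex on chromosome X (20 measured), Prdx4, Pdk3, Mbtps2 and Apoo fell by 0.46 ± 0.06, 0.24 ± 0.06, 0.22 ± 0.05 and 0.19 ± 0.05. Pcyt1b, named after its values were seen, rose by 0.32 ± 0.08 (list median -0.036, camera adjusted p = 0.148; the same 1 and 4 adjusted over the list alone). Not all of these changed genes are among the 20 measured genes nearest to Phex.

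The genes named from the lists were called on gene means, and single probe sets did not always pass. Of 155 such genes that passed, 71 had more than 1 probe set, and none had a probe set called in the opposite direction. All probe sets passed for 32 of them. In 33 genes only some passed: Angptl4, Apcdd1, Car12, Ccne1, Cd4, Col1a1, Ctsb, Cyp51, Dntt, Ece1, Edem1, Epcam, Fgf13, Fzd4, Gadd45b, Galnt3, Gsn, Igf1, Igfbp4, Igfbp7, Lgr6, Mmp14, Ndufa5, Nr4a2, Papss2, Pcsk5, Prdx4, Scd1, Selp, Sfrp5, Tgfb2, Tnfrsf11b and Xbp1. No probe set passed for 6, which were Cdkn1a, Ctsh, Dkk3, Fabp4, Nr4a3 and Pcyt1b. Of 84 genes with 1 probe set, 15 passed among gene means but not among all probe sets: Adipoq, Apoo, Ccl5, Ecel1, Gzmb, Ier3, Isg20, Mbtps2, Nfe2, Pdk3, Per1, Pth1r, Slc16a3, Thy1 and Vpreb1.

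Some calls on gene means were lost with 1 array fewer, with no change of direction. Few hung on 1 particular array: Il1b lost its call for 1 array only. Adipoq, Apoo, Ccl5, Cdkn1a, Thy1, Isg20, Sfrp5 and Slc16a3 each lost theirs for 7 arrays left out in turn. Of the genes named by the rule, 20 lost their call when 1 array was left out, as did 10 of 31 genes chosen after their values were seen. Without Hyp replicate 1, it was lost for Adipoq, Apoo, Ccl5, Cdkn1a, Ctsh, Dkk3, Ecel1, Gzmb, Ier3, Isg20, Mbtps2, Mki67, Pcyt1b, Pdk3, Pmp22, Pth1r, Rag1, Sfrp5, Slc16a3, Thy1 and Vpreb1. Without Hyp replicate 2, it was lost for Adipoq, Apoo, Ccl5, Cdkn1a, Col1a1, Ctsh, Dcstamp, Dkk3, Ecel1, Fabp4, Isg20, Mbtps2, Nfe2, Padi4, Per1, Pth1r, Sfrp5, Slc16a3 and Thy1. Without Hyp replicate 3, it was lost for Adipoq, Apoo, Ccl5, Col1a1, Dcstamp, Ecel1, Fabp4, Gzmb, Ier3, Isg20, Mki67, Nfe2, Pcyt1b, Pdk3, Per1, Ppp1r15a, Pth1r, Rag1, Selp, Sfrp5, Slc16a3 and Thy1. Without Hyp replicate 4, it was lost for Apoo, Ccl5, Cdkn1a, Dcstamp, Dkk3, Fabp4, Ier3, Isg20, Nfe2, Padi4, Pcyt1b, Per1, Pmp22, Ppp1r15a, Pth1r, Selp, Sfrp5 and Thy1. Without WT replicate 1, it was lost for Adipoq, Ccl5, Cdkn1a, Col1a1, Ctsh, Dcstamp, Dkk3, Ecel1, Fabp4, Gzmb, Ier3, Il1b, Isg20, Mki67, Nfe2, Padi4, Pcyt1b, Per1, Pmp22, Pth1r, Rag1, Selp, Sfrp5, Slc16a3, Thy1 and Vpreb1. Without WT replicate 2, it was lost for Adipoq, Apoo, Ccl5, Cdkn1a, Col1a1, Fabp4, Gzmb, Ier3, Isg20, Mki67, Nfe2, Per1, Sfrp5, Slc16a3, Thy1 and Vpreb1. Without WT replicate 3, it was lost for Adipoq, Apoo, Cdkn1a, Ctsh, Dkk3, Gzmb, Pcyt1b, Sfrp5 and Slc16a3. Without WT replicate 4, it was lost for Adipoq, Apoo, Ccl5, Cdkn1a, Col1a1, Ctsh, Dkk3, Fabp4, Gzmb, Isg20, Mbtps2, Mki67, Nfe2, Pcyt1b, Pdk3, Per1, Selp, Slc16a3, Thy1 and Vpreb1. Over the arrays whose removal ended the call, the differences of the former were Adipoq (-0.50 to -0.38), Apoo (-0.20 to -0.17), Ccl5 (0.18 to 0.27), Cdkn1a (-0.38 to -0.26), Dcstamp (-0.32 to -0.29), Fabp4 (0.42 to 0.59), Gzmb (0.26 to 0.36), Ier3 (0.27 to 0.37), Il1b (0.28), Mbtps2 (-0.21 to -0.20), Mki67 (0.26 to 0.28), Nfe2 (0.28 to 0.34), Padi4 (0.28 to 0.32), Pdk3 (-0.22 to -0.21), Per1 (0.43 to 0.57), Pmp22 (-0.43 to -0.37), Rag1 (-0.47 to -0.42), Selp (0.30 to 0.35), Thy1 (0.21 to 0.29) and Vpreb1 (-0.43 to -0.37), and those of the latter Col1a1 (0.36 to 0.45), Ctsh (-0.31 to -0.25), Dkk3 (-0.37 to -0.25), Ecel1 (0.23 to 0.26), Isg20 (0.38 to 0.52), Pcyt1b (0.26 to 0.32), Ppp1r15a (0.28 to 0.29), Pth1r (-0.26 to -0.23), Sfrp5 (0.16 to 0.24) and Slc16a3 (0.16 to 0.23).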

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

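The tests of muscle tissue, array scaling and mislabelling, of the share of osteoblast RNA, of marrow content, of array scaling for the marker lists and of cartilage were chosen after the results they bear on were seen, and the muscle covariate was added after the data were seen, with its bound written before that fit.

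In 432 groups of 4 arrays, 18 had 1 array far from the other 3 relative to the group's range, and chance marks about 1 in 20. The marks fell on Hyp replicate 4 (4), Hyp replicate 1, Hyp replicate 3 and WT replicate 4 (3 each), Hyp replicate 2 and WT replicate 1 (2 each) and WT replicate 3 (1). Among single probe sets, Thbs4 stood at -0.32 in WT replicate 4 against -2.02 to -1.87 in the other WT arrays, Sostdc1 at 1.30 in Hyp replicate 1 against 0.69 to 0.75, and Sost at -0.73 in Hyp replicate 4 against -0.87 to -0.85. Among gene means in Hyp arrays, replicate 4 stood apart for Ank (0.14 against 0.49 to 0.53), Cd36 (0.48 against 0.04 to 0.10) and Fzd4 (0.35 against 0.09 to 0.14). Hyp replicate 3 stood apart for Cdo1 (-0.41 against -0.58 to -0.56), Klf4 (-0.20 against -0.43 to -0.41) and Pcsk5 (-0.25 against -0.40 to -0.39). Hyp replicate 1 stood apart for Insig1 (-0.34 against -0.23 to -0.21) and Plvap (0.19 against 0.33 to 0.35), and Hyp replicate 2 for Ccne1 (0.07 against 0.13). Among gene means in WT arrays, replicate 1 stood apart for Cd34 (-0.26 against -0.10 to -0.08) and Smpd3 (0.72 against 0.40 to 0.44), replicate 3 for Mki67 (-0.01 against -0.31 to -0.28) and replicate 4 for Igfbp7 (-0.12 against -0.34 to -0.31). Of the list means, that of the non-collagenous matrix proteins stood at 0.05 in WT replicate 4 against -0.14 to -0.12, and that of glycolysis at 0.10 in Hyp replicate 2 against 0.01 to 0.02.

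Skeletal muscle genes were high in WT replicate 3. Of the 31 muscle list genes, 31 had their highest value in that array, with a median of 1.85 above the mean of the other WT arrays, and Acta1, Mylpf, Myh4 and Ckm stood at 2.79, 2.21, 1.48 and 1.35. Scaling or spread of the whole array as the whole cause is argued against by quantile normalization, after which 30 of the 31 genes still had their highest value there, with a median of 1.2 above the other WT arrays. A Hyp sample under a WT label is argued against by Phex expression, which parted the other 7 arrays by label, whether or not its probe sets read the deletion, and stood 5.94 above the highest Hyp array. Muscle tissue left on the bones of that sample may account for the pattern and stays open, as does a difference between the animals, which was not tested.

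Osteoblast markers were lower and macrophage, mast cell and eosinophil, endothelial and erythroid markers higher in Hyp bone. A smaller share of osteoblast RNA as the whole cause would raise the markers of other cell types alike, if their probe sets respond alike. The differences of 10 marrow and endothelial list means were uneven. They ran from -0.093 (B lineage) to 0.529 (mast cell and eosinophil), with an SD over the lists of 0.213 against at most 0.139 in the other splits of the 35. The splits cannot decide the cause, since any uneven difference between genotypes would give the real split the largest SD. More marrow as the whole cause was set against the 9 marrow lists in the same way (SD 0.218 against at most 0.142), with the same limit. First versions, which picked the macrophage list after its rise was seen, placed it 0.476 ± 0.04, 0.441 ± 0.038 and 0.347 ± 0.038 (SE) above the mean of 4, 6 and 8 other marrow lists. The mean of these 8 lists itself rose by 0.129 ± 0.023 (SE; exact permutation p = 0.0286). The 8 include the mast cell and eosinophil list and the erythroid list, whose rise is part of the pattern. The mean of the 6 lists without these differed by 0.034 ± 0.023 (SE; exact permutation p = 0.314). A rise of marrow lists in general was thus not shown. Muscle content is argued against by the fit with the muscle list mean as a covariate, in which all 5 lists kept their call, and scaling of the arrays by the 3 further normalizations, under each of which these 5 lists kept their call. A change in the number or state of the cell types that rose, or lower expression in osteoblasts, may underlie the pattern. More marrow or fewer osteoblasts stay open as a part of it, and as the whole cause if the lists respond unequally. A different dissection of the Hyp bones and a flatter response of dim probe sets were not tested.

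Col10a1 led the growth plate genes, and 6 of the 28 other measured genes of that list rose and 3 fell. Col10a1 rose by 2.468 ± 0.35 (SE) more than their mean, which excludes no explanation, since it was picked as the largest change of the list. For the others, whose mean differed by 0.099 ± 0.08 (SE; exact permutation p = 0.286), more cartilage stays open. A first, narrower set of 14 cartilage genes had been replaced by the whole list after its result was seen: there 13 of 14 lay above 0, 6 rose and none fell, with a mean difference of 0.401 ± 0.118 (exact permutation p = 0.0571) and Col10a1 2.166 ± 0.315 above it, so the choice of genes matters. A larger share of hypertrophic cartilage, or more Col10a1 in the same cells, may account for the Col10a1 difference, as may more cartilage in the Hyp samples, and these were not told apart.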

How the results depend on the processing

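The robust prior, the SD filter, the probe set with the largest SD, leaving both WT replicate 3 and Hyp replicate 2 out, and the muscle covariate were added after the data were seen. A filter on mean level, a variance trend and the choice of a probe set by mean level (with or without a shared-probe suffix) were not run, since the centred values hold no level. Signal over background is unknown for the same reason, so dim probe sets cannot be told from bright ones.

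Phex and Fgf23 kept their direction and call under all settings run, with gene means from -6.813 to -5.569 and from 5.48 to 6.633. The values -5.569 and 6.633 came from quantile normalization. Over 1452 higher and 1760 lower probe sets, the counts were 2206 higher and 2131 lower with array weights, 965 higher with the SD filter, 885 and 1153 without shared-probe suffixes (fewer probe sets tested), 458 and 844 at an adjusted p under 0.01 and 234 and 474 over 1.5-fold. With 1 array left out they ranged from 625 to 2125 higher and from 1055 to 1975 lower. The number of higher probe sets moved by over 1.5 times without any array but WT replicate 3: 907, 827, 791 and 914 without Hyp replicates 1, 2, 3 and 4, and 625, 958 and 791 without WT replicates 1, 2 and 4. The lower probe sets did so only without WT replicate 1 (1055). Other normalizations left between 36.4% and 40.6% of the calls higher, against 45.2%, while array weights gave 50.9% and leaving out WT replicate 3 gave 51.8%.

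The replicate number as a block gave 1267 higher and 1723 lower probe sets and 16 lists. Arrays of the same number had correlated deviations of 0.15, -0.04, 0.26 and 0.18 for numbers 1 to 4. As 1 of the 4 was not over 0.1 and the labels name no shared litter or day, the numbers are not read as pairs, though 5 of 8 arrays correlated best with their own number, a hint from the data that leaves shared handling open.

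Of the 14 lists past the threshold, 0 passed with an estimated correlation (adjusted p from 0.224 to 0.666). camera with the preset correlation called these 14, and fry called 19. The list medians, which this setting leaves as they were, are -0.498 (osteoblast), -0.193 (osteocyte), 0.399 (macrophage), 0.396 (mast cell), 0.368 (endothelial), 0.29 (erythroid), 0.155 (proliferation), 0.108 (inflammatory), -0.112 (unfolded protein response), -0.088 (sterol), 0.073 (cathepsin), -0.06 (BMP), -0.101 (B lineage) and -0.544 (muscle). The first 10 of these kept their call under every other setting, though the medians ranged from -0.305 to -0.129 for osteocyte markers, -0.249 to -0.052 for the unfolded protein response and -0.209 to -0.072 for sterol synthesis. The lowest of these came from the SD filter or, for osteocyte markers, the probe set with the largest SD, which both select variable probe sets, and -0.052 from probe sets without shared-probe suffix. With fry, B lineage (-0.101) and muscle (-0.544) lost theirs, and FGF targets (0.092), FGF ligands (0.026), the IGF system (0.109), T and NK cells (0.13), progenitors (0.111), nerve (0.009) and convertases (-0.019) gained one. The muscle list turned to 0.128 without WT replicate 3 and Hyp replicate 2 together (adjusted p = 0.734) and to 0.065 with its own mean as a covariate (adjusted p = 0.959), which removes it by construction. With both arrays left out or with the covariate, calls ended for BMP (-0.066 and -0.061) and cathepsins (0.089 and 0.085) and appeared for the glucocorticoid list (0.181 and 0.167) and neutrophils (0.093 and 0.10). BMP also lost its call with median centring (-0.071), quantile (-0.074) and cyclic loess normalization (-0.086), the SD filter (-0.084) and probe sets without shared-probe suffix (-0.059). B lineage lost its call with median centring (-0.112), cyclic loess (-0.095), the SD filter (-0.101) and the largest SD (-0.108), as cathepsins did with the largest SD (0.073). Calls appeared for neutrophils with array weights (0.107), quantile normalization (0.079) and the block (0.084), the glucocorticoid list with the block (0.122), progenitors without shared-probe suffix (0.111), and the IGF system (0.216) and convertases (-0.059) with the largest SD. Where calls were kept, medians moved by over 1.5 times for B lineage (-0.224 without both arrays, -0.203 with the covariate), cathepsins (0.261 with the SD filter), BMP (-0.095 with the largest SD) and muscle (-0.277 with quantile normalization, -0.289 with array weights). The cause of these changes was not tested.

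With 1 array left out, lists whose call changed had medians from -0.174 to -0.036 (B lineage), -0.089 to -0.046 (BMP), 0.053 to 0.09 (cathepsin), -0.828 to -0.102 (muscle), 0.073 to 0.11 (FGF targets), 0.079 to 0.141 (IGF), 0.069 to 0.165 (glucocorticoid), 0.116 to 0.147 (T and NK), 0.056 to 0.125 (interferon), 0.054 to 0.116 (neutrophil), 0.077 to 0.13 (progenitor) and -0.039 to 0.033 (convertase). Calls appeared without Hyp replicate 2 for FGF targets, IGF and glucocorticoid, without Hyp replicate 3 for T and NK cells, interferon and neutrophils, without WT replicate 1 for progenitors, without WT replicate 2 for interferon, without WT replicate 3 for glucocorticoid, neutrophils and convertases, and without WT replicate 4 for FGF targets and neutrophils. Of 170 values of probe sets and genes named by the rule, 142 lost a call under none of the settings run, and over 3203 values under alternatives, 3018 were the same, 154 lost and 31 gained the call, and 0 reversed. Of the other 28, all gene means, 20 lost a call without 1 array, as the report names them, and 8 only under other settings: Angptl4 (0.16) and Xbp1 (-0.21) without shared-probe suffix, Bank1 (0.28), Csf3r (0.29) and Tnfrsf11b (0.67) without both arrays, Ndufa2 (-0.23) and Ndufa5 (-0.24) with the SD filter and Nr4a3 (0.47) with the largest SD. Ndufa5 also lost it without both arrays (-0.20) and with the largest SD (-0.23). Of 31 genes chosen after their values were seen 12 lost a call, 2 of them only under other settings: Ece1 (0.29 without shared-probe suffix, 0.20 with the largest SD) and Maf (0.36 with the largest SD). The replicate block ended 4 gene calls and gave 5.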

Other observations

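The collagen folding test and the splits of the arrays were set out before their results were seen; the tests of resident macrophage and monocyte genes and of the genes beside Phex were chosen after values of some of their members had been seen, and the group of collagen folding genes itself was drawn up after P4ha1 and P4ha2 were seen to fall.

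Genes that fold, secrete and cross-link collagen were lower in Hyp bone. Of 26 measured genes other than P4ha1 and P4ha2, 17 fell and 1 rose, with a median of -0.395 (camera adjusted p = 1.43e-15 over 3 added lists; adjusted p = 0.051 with an estimated correlation). The list mean fell by 0.391 ± 0.037 (SE; exact permutation p = 0.0286), and the 4 Hyp arrays lay below the WT arrays. Kdelr3 fell by 0.85 ± 0.07 (SE), Rcn3 by 0.85 ± 0.07, P3h1 (prolyl 3-hydroxylase 1) by 0.84 ± 0.07, Plod2 (a collagen lysyl hydroxylase) by 0.81 ± 0.09, Lox (lysyl oxidase) by 0.78 ± 0.06, Serpinh1, the collagen chaperone, by 0.75 ± 0.06, and Sec24d and Sec23a, coat proteins of transport from the endoplasmic reticulum, by 0.72 ± 0.06 and 0.72 ± 0.06. Loxl1, another lysyl oxidase, rose by 0.51 ± 0.05. The difference of -0.391 is consistent with a hypothesis that both prolyl hydroxylases fell with other genes of collagen folding and cross-linking. The collagen list as a whole did not fall with them: 8 of 22 rose and 8 fell (median 0.02, camera adjusted p = 0.78). Which cells made each collagen was not examined, so this does not show whether collagens of the same cells were spared. A smaller share of matrix-forming cells was not excluded.

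Tissue-resident macrophage and blood monocyte genes were both higher. Of 15 resident genes 8 rose and 1 fell (camera adjusted p = 0.000256; adjusted p = 0.0532 with an estimated correlation), with Apoe at 0.73 ± 0.08 (SE), Selenop at 0.54 ± 0.06 and Maf at 0.43 ± 0.06, while Hpgd fell by 0.52 ± 0.05. Of 13 monocyte genes 5 rose (camera adjusted p = 0.00763; adjusted p = 0.0597 with an estimated correlation), with S100a4 at 0.68 ± 0.09 and Ace at 0.53 ± 0.05. The resident minus the monocyte mean differed by 0.061 ± 0.034 (SE; exact permutation p = 0.143), so the hypothesis that resident genes rose more was left open. Igf1 and Nr4a1, whose values had been seen, stand in these lists, and bone cells also express some of their genes.

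Genes beside Phex on the X chromosome were tested for a hypothesis that the deletion changes its neighbours. Of the 20 nearest measured genes, 10 on each side in the order of the reference table, 2 were called, both lower, or 10% against 12.9% of all other genes (Fisher's exact p = 1). The next measured genes on either side, Ptchd1 and Mbtps2, lay at 0.14 and -0.22, and Mbtps2 was called lower (limma adjusted p = 0.0186). The share called argues against a change in most of the nearest genes, though not in Mbtps2. The list of 20 genes fixed beforehand as neighbours is not the same set, and it held 4 genes that fell and 1 that rose. Only 2 of the nearest genes were called, so other calls of that list lie outside the nearest 20. Those calls do not bear on the genes beside Phex. The extent of the deletion was not examined.

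Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave 3212 changed probe sets, and the highest other gave 13. A share of 1 in 35 is the smallest that these splits can give. The other splits mix the genotypes within their groups, which widens the spread there and lowers their calls, so they are no measure of chance alone. For gene lists, 6 of the 35 splits gave at least the real 14, and the highest other gave 20, so chance cannot be excluded for the number of lists past camera's preset threshold. The 5 other splits with at least 14 lists each set 3 arrays of 1 genotype with 1 of the other, so part of the genotype difference stays in them. The 18 splits with 2 arrays of each genotype per group balance the genotypes, yet gave up to 11 lists. The split with 11 lists had 0 changed probe sets. Lists thus passed camera's preset threshold there without a contrast of genotypes. What raised the counts was not tested.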
